A study of Luffa aegyptiaca with 4 samples.

How the data were processed

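Transcript abundance was measured by RNA-seq in 4 samples of Luffa aegyptiaca, the sponge gourd: 2 control samples and 2 samples under heat stress, each described in the labels as biological replicate 1 or 2. The labels name the source only as tissue, and give neither the organ, the temperature nor the length of the treatment. Per the labels' protocols, total RNA was treated with DNase, converted to double-stranded cDNA, ligated to adapters, size-selected, amplified by PCR and sequenced on an Illumina instrument. No strand-marking step or molecular identifier is mentioned there.

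The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library), with 1 column per sample and 48619 rows of 1 transcript each. The submitters' processing notes name fastp 0.20.1, HISAT2 2.2.1 and StringTie 2.0. The genome build, the annotation, the StringTie settings and the treatment of multiply mapped reads are not given in the sources used here. The table was not filtered on abundance: 21129 rows were at 0 in every library. All 4 columns matched the title of 1 sample each, and 0 columns of other samples were present.

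FPKM values are not counts, and the sequencing depth of each library is unknown. Low values were searched for a common step that 1 read would be worth. Among rows under 0.3 FPKM in both libraries of a pair, the commonest ratio between them (within 0.0015 on the log2 scale) held at most 0.791% of the rows, so no relative depth was recovered and no counting interval or floor is given. A value of exactly 0 can be a failed estimate as well as an absent transcript, so such rows are described as listed at 0, with no fold.

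The values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. Rows with a mean over the 4 libraries of at least 1 FPKM were tested, which left 18186. A linear model with the group as its only term was fitted to all 4 libraries, with empirical Bayes moderation of the variance along a mean-variance trend. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. Changes are the difference in mean log2(FPKM + 1), heat minus control, with the standard error of the moderated fit. This scale understates the change of transcripts near 1 FPKM, so folds are also given as ratios of mean FPKM. With 2 libraries per group, the precision rests on variances shared across transcripts. The labels do not say whether replicates came from separate plants, so the p-values of single transcripts measure only the spread between these libraries. The lipoxygenase set test with a preset correlation and the random lists, described below, measure spread across transcripts instead.

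Only 29 rows carried a gene name, all of them lipoxygenases (LOX1 to LOX29). The other 48590 rows carried a number only, and no reference genome, annotation or table of gene names was used here. Of the 26 gene lists fixed before the data were examined, 1 (lipoxygenases) had members that could be matched. The other 25 (heat shock proteins, jasmonate pathway, photosynthesis, tissue markers and others) could not be tested. The rule for named genes, also fixed beforehand, took every lipoxygenase. Of the unnamed rows it took the 2 largest rises and the 2 largest falls past the threshold, with a mean of at least 5 FPKM and no overlap between the groups.

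The lipoxygenases were tested as a set with camera, at a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry. With an estimated correlation, camera also refers its statistic to the residual degrees of freedom of the 4 libraries, rather than to those of the transcripts. The median change of the lipoxygenases was compared with 10000 random lists of the same size matched on mean expression. The summed FPKM of the family was compared by an exact permutation test. Alternatives covered a pseudocount of 0.1, no filter on low values, a minimum mean of 5 FPKM, rescaling by the median of ratios, quantile normalization, moderation without a trend, a block for the replicate number, and the omission of each library in turn.

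The fit was tested on simulated data for the comparison of heat with control: 18186 transcripts with the observed control means and moderated variances, of which 200 were changed. Where the control level was too low for a fall, the change was made a rise. It recovered 82% of those changed by 1 on the log2 scale and 100% of those changed by 2. Simulated transcripts with a mean under 1 FPKM were not tested and counted as not recovered. These shares therefore mix the filter on abundance with the power of the fit. Of the 200 transcripts it called, 18 had not been changed, so the share of false calls in that simulation was above the nominal level. The simulation was a single draw with equal variance in both groups. Far fewer transcripts were changed in it than passed in the data, so its shares of recovered and false calls do not carry over to the reported calls. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.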

Results

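RNA-seq profiles were obtained from 2 control and 2 heat-stressed samples of Luffa aegyptiaca. Summed FPKM was 560000 and 567901 in control replicates 1 and 2, and 599611 and 551921 in heat replicates 1 and 2. The control libraries had 22556 and 22791 transcripts above 0, and the heat libraries 23562 and 24068. Read depth is unknown. The series title names the lipoxygenase family and its response to abiotic stress, and the comparison of heat with control addresses which members of the family changed. Lipoxygenases add molecular oxygen to polyunsaturated fatty acids and thereby open the pathways to jasmonic acid and other oxylipins. The positions of the transcripts in the genome were not analysed here.

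Lipoxygenase transcripts were mostly lower under heat. Of the 29 members in the table, 12 were abundant enough to be tested. Of these, 10 fell, LOX27 rose, and LOX29 did not pass the test (limma, adjusted p under the threshold over all 18186 transcripts). The counts adjusted over the list alone were also 10 lower and 1 higher. The summed FPKM of the family was 246.6 ± 8.65 (SD, n = 2) in control and 53.5 ± 2.05 (SD, n = 2) under heat, a 4.61-fold difference. It was lower in both heat libraries than in both controls, but an exact two-sided permutation test of 2 against 2 cannot go below p = 0.333, the value found.

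The most abundant members in control samples were LOX12 and LOX14, which together made up 64.0% and 66.6% of the family's FPKM in the control libraries. LOX12 (Laeg_LOX12.t01) fell 6.75-fold, from 93.1 ± 0.823 to 13.8 ± 1.08 FPKM (SD, n = 2 per group), a log2 change of -2.67 with a standard error of 0.11 (limma, adjusted p = 1.33e-05). LOX14 (Laeg_LOX14.t01) fell 9.59-fold, from 68.1 ± 9.29 to 7.10 ± 1.47 FPKM, a log2 change of -3.10 with a standard error of 0.17 (adjusted p = 2.94e-05). Under heat their joint share was 40.7% and 37.5% in the respective libraries.

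LOX15 and LOX11 were listed at 0 in both heat libraries. In control replicates 1 and 2, LOX15 stood at 21.9 and 16.1 FPKM, and LOX11 at 7.25 and 7.32 FPKM. Both passed the test (limma, adjusted p = 1.54e-05 for LOX15 and 2.53e-05 for LOX11). The values of 0 add no spread between the heat libraries, so these adjusted p-values do not allow for failed estimates. LOX8 stood at 4.55 and 4.18 FPKM in the controls. It was listed at 0 in heat replicate 1 and stood at 0.0640 in heat replicate 2 (adjusted p = 7.61e-05).

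A further 5 members fell from control levels between 3.26 and 13.4 FPKM. LOX9 went from 5.19 ± 0.244 to 0.276 ± 0.0788 FPKM (SD, n = 2 per group), an 18.8-fold fall. LOX3 fell 6.06-fold, LOX5 4.88-fold and LOX1 3.20-fold. LOX2 had the smallest fall, 1.96-fold from 13.4 ± 1.35 to 6.87 ± 1.15 FPKM, with a log2 change of -0.88 and a standard error of 0.16 (limma, adjusted p = 0.00338). The change of LOX2 was -0.66 after median-of-ratios rescaling and -0.65 after quantile normalization. Without control replicate 2 the change of LOX2 was -0.78 and its adjusted p 0.0533.

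LOX27 (Laeg_LOX27.t01) was the member that rose. It went from 10.9 ± 0.739 to 17.5 ± 1.07 FPKM (SD, n = 2 per group), a 1.60-fold rise, with a log2 change of 0.63 and a standard error of 0.13 (limma, adjusted p = 0.00479). The change of LOX27 was 0.86 after median-of-ratios rescaling and 0.79 after quantile normalization. Its share of the family's FPKM was 4.32% and 4.53% in the control libraries and 32.2% and 33.2% in the heat libraries. Without control replicate 1 the change was 0.57 and its adjusted p 0.0639. LOX29 stood at 2.32 ± 0.0451 FPKM in control and 2.15 ± 0.0972 under heat. The 95% confidence interval of its log2 change ran from -0.47 to 0.32 (adjusted p = 0.69), and the sign of the change turned under rescaling and under quantile normalization.

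**Figure D1:**
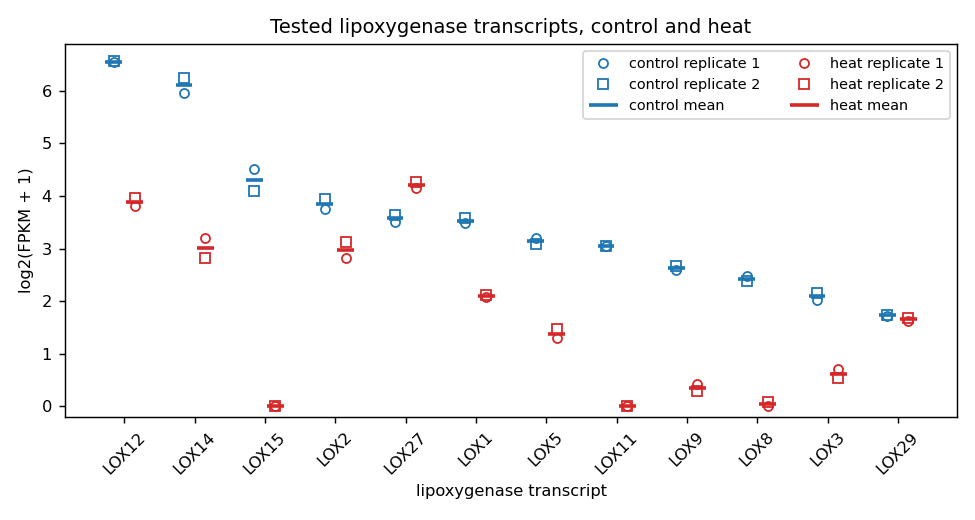
The 12 tested lipoxygenase transcripts on the x axis, ordered by control level, with abundance as log2(FPKM + 1) on the y axis. Open circles and squares are replicates 1 and 2 of the control (blue) and heat (red) samples, and bars are the means of the 2 libraries; the heat values lie below the control values for 11 transcripts, of which 10 passed the test and LOX29 did not, and above them for LOX27, while LOX15 and LOX11 are at 0 in both heat libraries.

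The remaining 17 lipoxygenases were below the minimum for testing, and 9 of them (LOX4, LOX6, LOX7, LOX17, LOX19, LOX20, LOX21, LOX22 and LOX28) were listed at 0 in every library. Of the other 8, LOX16, LOX18, LOX26 and LOX10 had the higher mean in control. LOX16 stood at 0.578 and 0.678 FPKM in the controls and was listed at 0 in both heat libraries. LOX23, LOX24 and LOX25 were listed at 0 in both controls and lay between 0.0338 and 0.146 FPKM in the heat libraries. LOX13 was above 0 only in heat replicate 2, at 0.0413 FPKM. When all 20 members above 0 were tested, LOX16, LOX18 and LOX26 joined the members that fell. LOX10, LOX13, LOX23, LOX24 and LOX25 did not pass the test. The mean of LOX18 was 0.273 FPKM in control and 0.0459 under heat, where replicate 2 was listed at 0. The mean of LOX26 was 0.354 FPKM in control and 0.0113 under heat, where replicate 1 was listed at 0. Read depth is unknown and a value of 0 can be a failed estimate. The added calls of LOX16, LOX18 and LOX26 are therefore uncertain.

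As a set, the 12 tested lipoxygenases had a median log2 change of -2.02, or -1.82 relative to the median of all tested transcripts (-0.20). That median was -1.62 without LOX11 and LOX15, which were listed at 0 under heat, -2.58 with a pseudocount of 0.1 and -0.79 over all 20 members above 0. Their set test against all other transcripts gave p = 0.00272 (camera, preset correlation of 0.01, downward). The call was lost with the correlation between members estimated, at 0.0519 (camera, p = 0.128). That setting also refers the statistic to the residual degrees of freedom of the libraries. The loss therefore cannot be credited to correlation between members alone. The directional fry test of limma asks whether the members move one way on balance and does not compare them with other genes. It gave an adjusted p of 0.000133, equal to the raw value because 1 list was tested. Lipoxygenases can be close copies of each other, and how reads shared between copies were assigned is not stated. Values of single members are therefore uncertain. The family's sum is free of this limit only for reads moved among the named members between copies of like length.

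The transcriptome as a whole differed strongly between the groups. Of 18186 tested transcripts, 5617 (30.9%) were higher and 7735 (42.5%) lower under heat, and 4834 did not pass the test (limma, Benjamini-Hochberg adjustment). A change of at least 1 on the log2 scale was seen in 3465 of the higher and 5195 of the lower transcripts. Among the largest changes the order was the other way: 169 transcripts rose and 42 fell by at least 5 on the log2 scale. The split between higher and lower depended on scaling. The median tested transcript moved by -0.20 on the log2 scale with the values as deposited and by 0.01 after rescaling by the median of ratios, where 6662 transcripts were higher and 6643 lower. At a change of at least 1 on the log2 scale the rescaled numbers were 4184 higher and 4366 lower.

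The groups were separated far more than the replicates. Across the tested transcripts, Pearson's r of log2(FPKM + 1) was 0.987 between the control replicates and 0.976 between the heat replicates, and lay between 0.578 and 0.603 for the pairs of a control and a heat library. These are correlations across transcripts, which are not independent replicates. The first principal component, which separated control from heat, held 95.5% of the variance. The median absolute difference of a transcript was 0.12 between the control replicates, 0.21 between the heat replicates and at least 0.95 between libraries of different groups, on the log2 scale. The labels give no sequencing batch or date, so a batch shared by a group could not be examined.

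**Figure D2:**
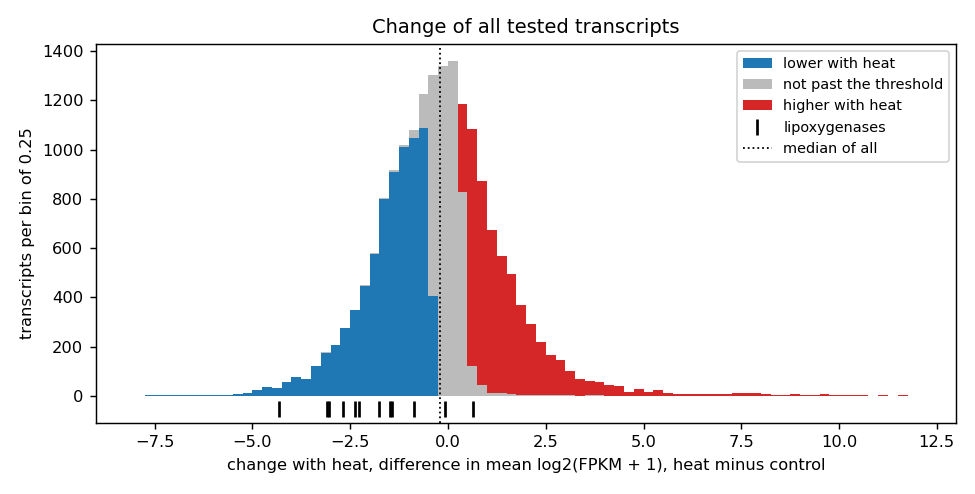
Histogram of the change with heat of the 18186 tested transcripts; the x axis is the difference in mean log2(FPKM + 1), heat minus control, and the y axis the number of transcripts per bin of 0.25. Blue and red bars are the 7735 lower and 5617 higher transcripts, grey bars those not past the threshold, ticks the 12 lipoxygenases and the dotted line the median of -0.20; most lipoxygenases lie to the left of that line.

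The most abundant transcripts also differed between the groups. Of the 100 most abundant transcripts in the control samples and the 100 most abundant under heat, 36 were in both lists. Of the control list, 73 were lower under heat, a number that was 60 after median-of-ratios rescaling and 83 after quantile normalization. The number was also smaller without either control replicate, where the spread is taken from fewer libraries. Of the heat list, 66 were higher under heat, and 15 had a control mean under 1 FPKM. These lists were ranked on the same libraries, so their directions are not independent evidence. The most abundant transcript was the same in all 4 libraries. It took 4.11% and 4.28% of summed FPKM in the controls and 1.60% and 1.37% under heat.

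The largest rises among unnamed transcripts were those of Luffa_aegyptiaca45871.t01 and Luffa_aegyptiaca45876.t01. The former stood at 0.226 and 0.555 FPKM in the controls and at 4270 and 3954 FPKM under heat, a log2 change of 11.54 with a standard error of 0.15 (limma, adjusted p = 1.03e-06). The latter stood at 0.835 and 1.81 FPKM in the controls and at 5854 and 4212 FPKM under heat, a log2 change of 11.10 with a standard error of 0.25 (adjusted p = 3.10e-06). The largest falls were those of Luffa_aegyptiaca45528.t01 and Luffa_aegyptiaca19054.t01. The former went from 212 and 177 FPKM to being listed at 0 in both heat libraries (adjusted p = 1.85e-06, with the same limit as for LOX11 and LOX15). The latter went from 269 and 287 FPKM to 0.620 and 0.577 FPKM, a log2 change of -7.45 with a standard error of 0.11 (adjusted p = 1.21e-06). The table pairs none of these numbers with a gene name.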

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

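Of the 11 alternatives, none turned the direction of a lipoxygenase that passed the test, and none made a transcript called with the values as deposited pass in the opposite direction. The number of transcripts past the threshold lay between 9687 and 14924, against 13352 as reported. With an estimated correlation and the residual degrees of freedom of the libraries, the family's set call was lost (camera, p = 0.128, values as deposited). With the preset correlation, camera gave p between 0.00128 and 0.0467 in the alternatives that kept all 4 libraries. The highest p came with a minimum mean of 5 FPKM. Under that minimum, 6 lipoxygenases were tested, of which 5 fell, because fewer members remained. LOX29, which did not pass the test, changed sign to 0.10 after median-of-ratios rescaling and to 0.24 after quantile normalization. The ratio of the family's summed FPKM, control over heat, was 3.89 after rescaling, against 4.61. The highest correlation between a control and a heat library was 0.522 with a pseudocount of 0.1 and 0.788 with no filter on low values, against 0.603, where rows at 0 in several libraries enter. Leaving out 1 library at a time left a single sample in one group, which is then assumed to vary like the other group; the number of lipoxygenases that rose was 0 to 1, that of those that fell 9 to 10, and that of all calls 10200 to 12738. LOX27 lost its call without control replicate 1 and LOX2 without control replicate 2. Their log2 changes moved by less than their standard errors, from 0.63 to 0.57 and from -0.88 to -0.78. These fits take their spread from fewer libraries, so the lost calls do not show that either rests on 1 particular library. With a replicate block, 13149 transcripts passed, and 10 lipoxygenases fell and 1 rose. The block changed no lipoxygenase call. Across transcripts, the deviations of same-numbered libraries had a correlation of -0.07, which shows no large shared effect. That value cannot exclude a small one, and the labels do not say whether the replicates pair. Of the transcripts called with the values as deposited, 91.8% were called in the same direction after rescaling. Across the alternatives that kept all 4 libraries, this share was highest with a pseudocount of 0.1, at 98.1%. It was lowest, at 71.6%, with a minimum mean of 5 FPKM, where fewer transcripts were tested. The alternatives planned for the other 25 gene lists were not run, since no row carried a matching name. Read depth is unknown, so its limit on the values under 1 FPKM cannot be stated.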

Other observations

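The tests on transcripts at 0 in single libraries, on losses between the controls and on the family's summed FPKM were chosen after the results they measure had been seen.

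Some transcripts were present in one group and listed at 0 in the other. At 5 FPKM or more in both libraries of a group, 139 transcripts were listed at 0 in both controls and present under heat, and 38 the reverse. At 50 FPKM or more the numbers were 37 and 1. LOX11 and LOX15 belong to the transcripts present in control and at 0 under heat.

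The log2 changes of transcripts with neighbouring ID numbers were weakly correlated. The log2 changes of 10169 pairs of tested transcripts with consecutive numbers had a Pearson's r of 0.28 across pairs, against 0.07 at a distance of 5 numbers and 0.01 at a distance of 50. Of the 100 transcripts with the largest rises, 34 had another of the 100 within 10 numbers. In 10000 random draws of 100 tested transcripts the mean was 5.30 and the highest value 20. Of the 100 with the largest falls, 16 had another within 10 numbers, above that mean but below the highest random value. Whether the numbers follow genome order is not stated in the sources used here.

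Among transcripts with a mean of at least 50 FPKM, heat replicate 1 exceeded heat replicate 2 by a median of 0.15 on the log2 scale, while the corresponding difference in the controls was -0.00244.

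The low correlation between control and heat libraries, at most 0.603 against at least 0.976 within groups, is a first pattern to weigh. No technical explanation for it was excluded. The heat treatment remains open as an explanation, and so does another tissue or developmental stage in one group: 0 rows matched a tissue marker list, the labels name no organ, and these cannot be told apart here.

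The transcripts listed at 0 in one group are a second pattern. Failed estimates striking single libraries at random would give 0.0368 such transcripts from the rate within replicate pairs (0.127%), and 177 were found, 4809 times as many. Both controls listed fewer transcripts between 0 and 0.5 FPKM (3591 and 3874) than both heat libraries (4621 and 4734), the direction that lower depth would give. Against depth as the whole cause, 0.0964% and 0.0646% of the transcripts at 5 FPKM or more in one control were listed at 0 in the other, while 1.29% of those at 5 FPKM or more in both heat libraries were at 0 in both controls. Estimates that fail at the same transcript in both libraries of a group remain open, as do a part played by depth for short transcripts, whose lengths the table does not give, and a change with the treatment.

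The lower lipoxygenase transcripts under heat are the third pattern. The median log2 change of the 12 members, -2.02, lay below that of each of 10000 random lists matched on mean expression (percentile 0; central 95% of lists from -1.20 to 0.69), which argues against a fall shared by transcripts of this abundance. Random lists treat members as independent and measure spread across transcripts. The camera test with an estimated correlation and the residual degrees of freedom of the libraries gave p = 0.128. How far the family differs from other transcripts is therefore less certain than the falls of its members. Reads moved between near-identical copies of like length would leave the family's sum in place. Members with the higher mean under heat gained 6.84 FPKM, whereas the others lost 199.97. The sum differed by 22.3 times the larger replicate SD (n = 2, where an exact permutation test cannot go below p = 0.333). Such moves alone therefore do not account for the fall of the sum. The sum cannot exclude them for single members such as LOX11 and LOX15. Reads moved between copies of unlike length, which the table does not give, or to copies outside the 29 named rows remain open. A response to heat may explain the fall, as a hypothesis, and a difference in tissue between the groups remains open as in the first pattern.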
